A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

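Yrr1 is a zinc cluster transcription factor of budding yeast that activates drug resistance genes. The series holds 24 sequencing libraries from Saccharomyces cerevisiae S96 cells that lack their own YRR1 gene and carry a Myc-tagged YRR1 allele: the allele of strain YJM789, the allele of S96 itself, or the S96 allele with the change I775E. Cells were grown in rich medium (YPD) or in YPD with 0.25 µg/ml 4-nitroquinoline-N-oxide (4NQO), a DNA-damaging drug, for 2.5 h, per the labels' protocols. Each of the 6 allele and medium groups has 3 anti-Myc chromatin immunoprecipitation (ChIP) libraries and 1 input library, so there are 18 ChIP and 6 input libraries. The labels' design text speaks of triplicate cultures and the growth protocol of duplicate cultures, so p-values measure the spread between libraries, which may be partly technical. No library of an untagged strain was analysed here.

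The submitters' processing notes name CASAVA 1.7, Bowtie2 2.2.3, MACS2 2.1.0 and the genome build sacCer3, without saying which step used which. All coordinates are those of the deposited tables, on sacCer3, counted from 1, and a region that the tables start before position 1 is printed from 1. Neither read counts nor read totals are in the tables used here, so the depth of each library is unknown and no counting interval could be given. The depth scale that shows is the background pileup of the deposited MACS2 lists, which lay between 34.9 and 45.8 per library after scaling to the smaller of ChIP and input.

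MACS2 peaks were deposited per ChIP library against its group's input, under a pair of parameter sets that the tables mark mn and m2 without explanation. Each deposited peak has a pileup signal at its summit, a fold enrichment over local background as a ratio, and −log10 p and q values, per the file headers. The lowest −log10 q was 1.3. A further deposited list holds the MACS2 peaks of the reverse test, in which input exceeded ChIP. CisGenome peaks were deposited per group under 4 settings, with a log2 fold change, a score (maximum T), a −log10 Poisson p-value and a false discovery rate (FDR), per the file headers; whether the 3 libraries were pooled is not given in the sources used here. A deposited region table gives, for each of 1711 regions and each ChIP library, a signal that the authors call the rise of the climax over background. In every entry it equals the ChIP minus input coverage score at the strongest point less its mean over the surroundings, with a largest departure of 1.0e-12. The rise is never negative and is empty where no such point is listed (7.3% of entries in the mn set). Empty regions were not spread evenly over the groups. They averaged 281.3 ± 22 per library for S96 in YPD, the most of any group. YJM789 in YPD had 149.3 and S96 in 4NQO 103.7, and S96-I775E in YPD and 4NQO had 78.33 and 70.33. YJM789 in 4NQO had 68.33. Every region covers at least 1 listed peak: 1090 a MACS2 ChIP peak, 810 a MACS2 peak of the reverse test and 356 a CisGenome peak, and regions of several kinds occur. Of these regions, 18 are mitochondrial and 1 is the 2-micron plasmid. At these, and at the ribosomal DNA, the reverse MACS2 test often calls input above ChIP although the rise is high, because the rise measures a local peak above its own surroundings. The tables hold 10 further columns of values per peak or library that were not used.

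From these tables, peaks of the mn set were merged within each group, and a region counted as bound when it had a peak in at least 2 of the 3 libraries. Overlaps between groups were counted with bedtools 2.31.1 at a minimum of 1 bp and set against 10000 random placements of the same lengths on the same chromosomes (one-sided; the smallest p these can give is 0.0001). A gene was assigned to a region when its start codon lay at most 500 bp downstream of the region's centre, and a region with no such gene is named after the gene it lies in ("body") or the nearest gene ("near"). The 6 gene lists fixed before the data were examined (Yrr1 and pleiotropic drug resistance targets, respiration, DNA damage, oxidative stress, highly transcribed genes, general stress) were tested with a one-sided Fisher's exact test and Benjamini-Hochberg adjustment over the 6 lists of each region set, in 168 tests. They matched 39, 52, 31, 22, 171 and 20 genes in that order, and 1 drug resistance gene (AAD6) was not matched. The background was 6002 nuclear protein-coding genes for bound regions, and 450 genes with a tested region for differences. Names starting with YNC are the annotation's names for noncoding genes, most of them tRNA genes.

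Differences between groups were tested on log2(rise + 1) with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend). All 6 ChIP groups entered one fit with 1 coefficient per group, and p-values were adjusted by Benjamini-Hochberg over the regions of each of 11 comparisons, at 0.05. Regions with at least 2 values in each group were tested: 1350, leaving 361 untested. Adjusted p-values in the text are limma's unless another test is named. Log2 changes are on this scale and understate changes of low regions. The design fixed before the data were examined foresaw a count test where counts were given. The use of the rise, the mn set, the filter and the trend were chosen after the tables were seen. The 3 ChIP libraries of a group share 1 input, so an error of that input moves all 3 together and the p-values do not cover it. The rise is not scaled to a common median: the median log2 change over the 1350 regions was −0.19 for YJM789 against S96 in YPD, 0.18 in 4NQO, −0.24 for S96-I775E against S96 in YPD, −0.03 in 4NQO, −0.05 for S96-I775E against YJM789 in YPD, −0.18 in 4NQO, and 0.25, −0.13 and 0.09 for 4NQO against YPD in YJM789, S96 and S96-I775E. It was 0.36 and 0.21 for the differences of the 4NQO response of YJM789 and of S96-I775E from that of S96. Counts with library medians set equal therefore stand beside the main counts.

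For each comparison the 10 regions with the largest change in each direction among those past the threshold, 1 per gene, are named, together with YRR1, the regions bound in every group and the members of the gene lists. On simulated values for YJM789 against S96 in YPD (1350 regions, 200 changed), the fit recovered 56% of 2-fold and 94% of 4-fold changes, 2% of its calls were false, and it made 0 calls when nothing was changed. The simulated noise was independent between regions and libraries, with no error of a shared input and no shift of whole libraries. These rates therefore do not cover such errors in the real data. The overlap count found 30 of 30 planted intervals. The Yrr1 recognition sequence was searched as WCCGYKKWW on both strands, and copies of regions elsewhere in the genome were searched with blastn 2.17.0 (95% identity over 50% of the length). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. Alternatives were the m2 set, other pseudocounts, filters, thresholds, overlaps and promoter lengths, equal library medians, fits of the compared groups alone, a replicate block, and each library left out in turn. A named region counts as keeping its call under all other settings when it did so in every such fit that held it. Mitochondrial and plasmid regions are absent from the fit of nuclear regions only. The linear scale, the stricter threshold and the fold limit do not enter these counts.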

Results

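Binding of Myc-tagged Yrr1 was measured by ChIP-seq in 18 libraries, 3 for each of 3 YRR1 alleles in YPD and in 4NQO, each set against the 1 input library of its group. The alleles were those of YJM789 and of the laboratory strain S96, and the S96 allele with the single amino acid change I775E. Read depth is unknown, and the values below are the rise (ChIP minus input coverage at a region's strongest point, above its surroundings) or MACS2 fold enrichment, each given as mean ± SD with n = 3 libraries unless stated. Across the 9 comparisons of 2 groups below, the libraries of the compared groups did not overlap for 175 of 177 named results, the exceptions being near YNCL0049C (S96-I775E against S96 in YPD) and near CCW12 (4NQO against YPD in S96). Chance gives such a separation for 10% of regions with 3 against 3, and these regions were named because they passed the test.

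YRR1 itself, whose promoter Yrr1 binds (chromosome XV 642006 to 642721, sacCer3, 371 bp from the YRR1 start codon and also upstream of DDP1), carried a MACS2 peak in 16 of 18 libraries. Only 1 of 3 YJM789 libraries in YPD had one. Its rise was 141.3 ± 5.01 for S96 in YPD, 77.71 ± 43.4 for S96 in 4NQO, 48.81 ± 25.3 and 40.02 ± 10.8 for YJM789 in YPD and 4NQO, and 33.93 ± 14.8 and 40.89 ± 3.7 for S96-I775E. The cells carry YRR1 as an introduced copy, which the reference does not hold as a separate sequence, so signal at this region cannot be assigned to the genomic or the introduced promoter.

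In all 6 groups, 3 regions had a peak in at least 2 of 3 libraries: IRT1, SNQ2 and SNG1. The strongest by mean fold over all libraries was inside IRT1 (chromosome X 606408 to 607949), a noncoding RNA gene transcribed across the promoter of the meiosis regulator IME1. It had a peak in 18 of 18 libraries with a mean fold enrichment of 3.93, its strongest point at 607352 and a match to the Yrr1 recognition sequence, ATACGCGGA, at 607349. The next was the promoter of SNQ2 (IV 464940 to 465905, 496 bp from its start codon), which encodes the membrane transporter that exports 4NQO. It too had a peak in 18 of 18 libraries, at a mean fold of 3.23. The region held 4 matches to the recognition sequence, of which those at 465334 and 465335 overlap. In all 6 S96-I775E libraries its fold, at least 3.17, was above that of IRT1. SNG1 (VII 893849 to 894948, 258 bp from its start codon), a gene for resistance to nitrosoguanidine, had a peak in 16 of 18 libraries at a mean fold of 2.04. Its region held a match at 894481, and that of YRR1 overlapping matches at 642252 and 642253. SNQ2 held 196.3 ± 4.78 and 242.0 ± 28.4 for YJM789 in YPD and 4NQO, 177.3 ± 9.83 and 172.5 ± 11.7 for S96, and 166.1 ± 16.3 and 226.0 ± 8.86 for S96-I775E. IRT1 held 231.8 ± 19.0 and 242.9 ± 24.4, 342.4 ± 19.8 and 259.5 ± 31.9, and 98.93 ± 5.09 and 124.6 ± 26.7 in the same order, and SNG1 held 70.92 ± 9.11 and 132.8 ± 9.05, 107.5 ± 16.4 and 71.78 ± 14.0, and 54.26 ± 9.29 and 50.42 ± 12.1.

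**Figure D1:**
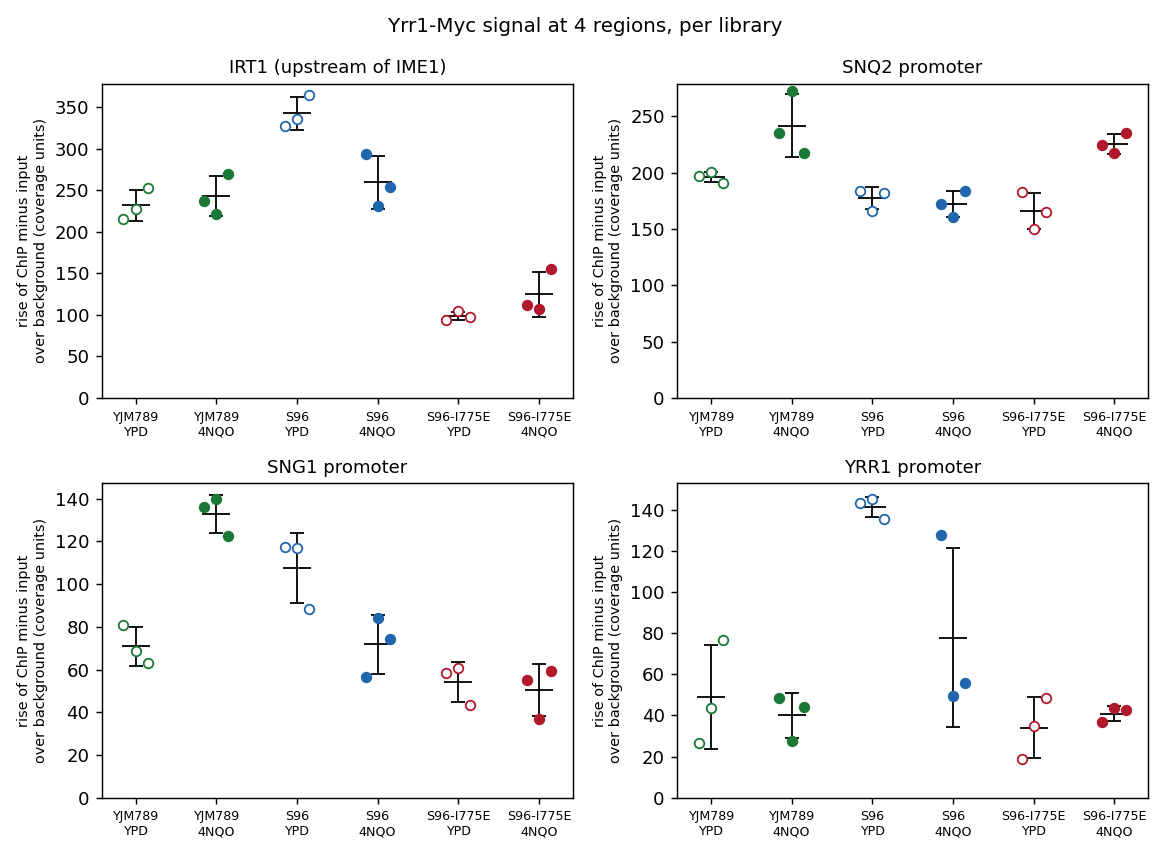
Rise of ChIP minus input over background, in coverage units, at the IRT1, SNQ2, SNG1 and YRR1 regions for each of 18 libraries (points; open YPD, filled 4NQO), with mean and SD (n = 3) as bars, by allele and medium. At IRT1 the 6 S96-I775E libraries lie below all 12 others, and at YRR1 the 3 S96 libraries in YPD lie above all 15 others.

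The first question was which regions each allele bound in each medium. Bound regions, with a peak in at least 2 of 3 libraries, numbered 4 for YJM789 in YPD, 273 for YJM789 in 4NQO, 75 and 61 for S96 in YPD and 4NQO, and 36 and 31 for S96-I775E. Peaks per library averaged 8.333 ± 3.21 for YJM789 in YPD, 323.3 ± 259 for YJM789 in 4NQO, 105 ± 80.9 and 102 ± 60.7 for S96, and 70 ± 40 and 38 ± 12.3 for S96-I775E. The 273 regions of YJM789 in 4NQO rest on replicates 1 and 2, with 518 and 422 peaks against 30 in replicate 3, and fell to 21 without replicate 1 and 22 without replicate 2. S96 in YPD went from 75 to 13 without replicate 2 and 15 without replicate 3, and S96 in 4NQO from 61 to 27 and 9 without those. S96-I775E in YPD went from 36 to 21, 13 and 13 without replicates 1, 2 and 3, and in 4NQO from 31 to 16 and 20 without replicates 1 and 2. At a fold of at least 2 the numbers were 2, 42, 5, 5, 2 and 8.

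**Figure D2:**
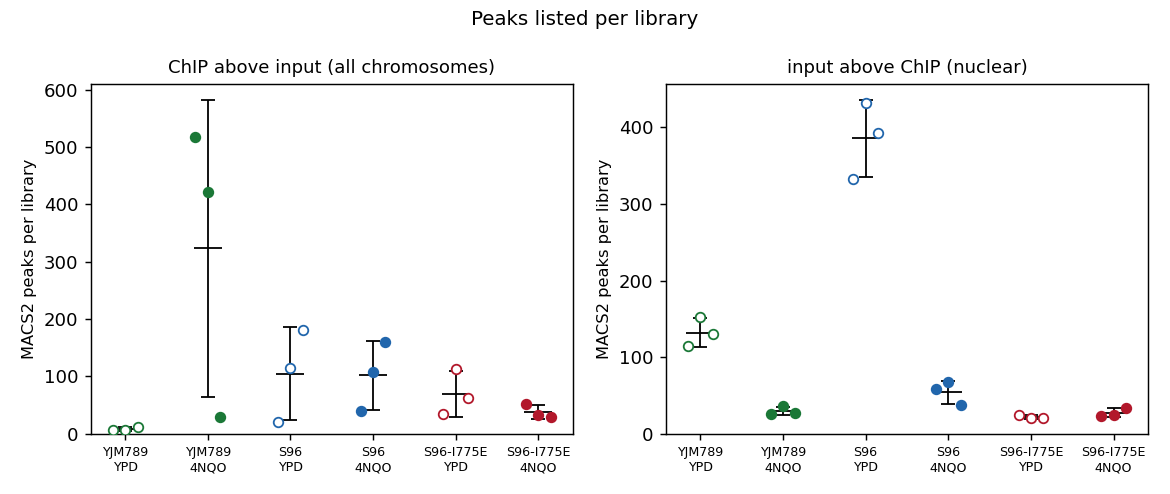
MACS2 peaks per library with ChIP above input (left, all chromosomes) and with input above ChIP (right, nuclear chromosomes), as points for each of 18 libraries with mean and SD (n = 3), by allele and medium. Replicate 3 of YJM789 in 4NQO has 30 peaks against 518 and 422 in the other libraries of its group, and S96 in YPD has the most regions with input above ChIP.

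Bound regions recurred between groups. All 4 regions of YJM789 in YPD were also bound by S96 in YPD (0.03 by random placement) and by S96-I775E in YPD (0.02). In 4NQO, 37 of 61 S96 regions and 23 of 31 S96-I775E regions were bound by YJM789 (1.35 and 0.71 by random placement), and 13 of 31 S96-I775E regions by S96 (0.14). Between media, 15 of 61 S96 regions in 4NQO were bound in YPD (0.32), as were 9 of 31 S96-I775E regions (0.08), and 3 of 4 YJM789 regions in YPD were bound in 4NQO (0.1, permutation p = 0.0003). S96 and S96-I775E in YPD shared 12 of 36 regions (0.21). For all of these except the YJM789 pair permutation p was 0.0001, the smallest that the placements can give. The placements were uniform along chromosomes, whereas peaks gathered at tRNA genes and bodies of highly transcribed genes (below). The overlaps therefore cannot separate recurrent Yrr1 binding from background that recurs at such loci.

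The positions of the bound regions were set against random placement. Of 372 regions bound in any group, 77 (20.7%, 95% interval 16.7 to 25.2) lay within 500 bp upstream of a gene, against 21.3% of random placements (permutation p = 0.6311). In YPD the promoter share was higher than at random, at 26 of 75 for S96 (34.7%, permutation p = 0.0064), 15 of 36 for S96-I775E (41.7%, permutation p = 0.0052) and 3 of 4 for YJM789 (permutation p = 0.0333). In 4NQO it was 21.3% for S96 (permutation p = 0.5292), 32.3% for S96-I775E (permutation p = 0.1065) and 17.6% for YJM789 (permutation p = 0.9462). Whether the share differs between media was not tested. Counted apart from these positions, 76 regions or 20.4% lay at tRNA genes, against 1.4% at random (permutation p = 0.0001, the smallest possible). A region at a tRNA gene can also count as promoter or coding. How far such regions make up the promoter shares was not tested. The tRNA share was 57.3% (43 of 75) for S96 in YPD, 18 of 36 for S96-I775E in YPD and 0 of 4 for YJM789 in YPD. In 4NQO it was 24.6% (15 of 61) for S96 and 25.8% (8 of 31) for S96-I775E. It was 4.4% (12 of 273) for YJM789 in 4NQO, where 81.7% (223 of 273) lay in coding sequence (72.6% at random, permutation p = 0.0010). By promoter, drug resistance targets were the only list past the threshold in bound regions, in all 6 groups. YJM789 in YPD had SNG1 and SNQ2 (adjusted p = 0.00364 by Fisher's exact test). YJM789 in 4NQO had ICT1, SNG1, SNQ2 and YRR1 (0.00246), S96 had SNG1, SNQ2 and YRR1 in YPD (0.00863) and SNG1 and YRR1 in 4NQO (0.028, where the bound SNQ2 region has its centre beyond the 500 bp limit), and S96-I775E had SNG1, SNQ2 and YRR1 in both (0.00246 and 0.000656). These calls depend on the promoter length: with promoters of 250 bp, shorter than the distances of SNQ2, YRR1 and SNG1, 0 of 168 list tests by promoter passed, against 8 at 500 bp (these 6 and 2 for regions that differ between groups). Highly transcribed genes were enriched by overlap with the gene body: 51 genes in YJM789 in 4NQO (adjusted p = 1.61e-31), among them the glycolytic genes PDC1 and ENO2, then 11 and 16 in S96 in YPD and 4NQO (3.84e-10 and 4.29e-15) and 7 and 4 in S96-I775E (2.35e-07 and 0.00531). Respiration, DNA damage, oxidative stress and general stress genes passed in no bound set, by promoter or by body. CisGenome, the second caller, gave 250 regions, of which 92 (36.8%) shared at least 1 bp with the MACS2 regions of their group. By group the share ran from 18.3% (S96-I775E in 4NQO) to 66.7% (YJM789 in either medium). Of 1041 deposited CisGenome peaks, 127 had an FDR below 1. Only 1 had an FDR of 0, and the lowest other FDR was 0.827. The share is thus an overlap with listed regions, almost all of them not significant by the FDR of CisGenome.

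The comparison of YJM789 with S96 in YPD asks how the natural alleles differ without drug. YRR1 and IRT1 were lower with the YJM789 allele, at −1.64 ± 0.35 (SE) on the log2 scale (adjusted p = 0.0113) and −0.56 ± 0.11 (adjusted p = 0.00872). SNQ2 did not pass (0.15 ± 0.09, adjusted p = 0.394), nor did SNG1 (−0.59 ± 0.21, adjusted p = 0.148). Further regions lower in YJM789 were the promoter of CHD1, a chromatin remodeller (−1.41), the promoter of SRO9 (−1.58), the bodies of RIM8, an arrestin of the pH pathway (−1.52), and UTH1 (−1.35), and a region near CCW12, a cell wall gene (−1.65). At RIM8 and UTH1 MACS2 called input above ChIP in 2 of 3 S96 libraries, the group with the higher rise, and ChIP above input in 0 of 3. Higher ones were the promoters of YNL146C-A (1.74) and DCD1, the deoxycytidylate deaminase gene (50.52 ± 9.59 against 20.72 ± 8.1), where the strongest point lies in the proline tRNA gene SUF8, and 3 mitochondrial regions, including COX1 (0.72), at which MACS2 called input above ChIP in all 3 libraries of either group. YNL146C-A has values in 2 of 3 YJM789 libraries and turned to −0.17 with empty values as 0.

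In all, 7 regions were higher and 21 lower in YJM789 than in S96 in YPD (limma, 1350 regions), or 9 and 7 with library medians set equal and 53 and 39 with empty values as 0, both with more higher than lower. Of the higher and lower regions, 0 of 7 and 5 of 21 had a peak in at least 2 libraries of the higher group. Input above ChIP in at least 2 of them stood at 3 of 7 and 4 of 21. Of 3 tested drug resistance regions 1 was lower over all regions, and 2 (YRR1 and SNG1) adjusted over the list alone, and general stress had 1 lower (TPS1) on the latter count. The general stress list has only 1 tested region (TPS1), so here and below its p-value on that count is in effect unadjusted. The 28 calls became 5 and 7 without YJM789 replicates 1 and 3, and 6 (3 higher and 3 lower) and 15 without S96 replicates 2 and 3. Of 18 named regions, 1 (near BI3, mitochondrial) kept its call with each library left out, and 0 under all other settings too. YRR1 lost it without YJM789 replicate 1 (−1.28, adjusted p = 0.105) or S96 replicate 2 (−1.62, 0.0751), and IRT1 without YJM789 replicate 1 (−0.51, 0.0625). YRR1 also lost it in the m2 set (−1.34, 0.131), and IRT1 with library medians set equal (−0.38, 0.134).

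In 4NQO, the same comparison shows whether the alleles differ under the drug. The promoters of both transport and resistance genes SNQ2 (0.48 ± 0.09, adjusted p = 0.00109) and SNG1 (0.90 ± 0.21, adjusted p = 0.0131) were higher with the YJM789 allele, while IRT1 did not differ past the threshold (−0.09 ± 0.11, adjusted p = 0.699), nor did YRR1 (−0.85 ± 0.35, adjusted p = 0.188). Signal was also higher in YJM789 in the bodies of HPF1, a mannoprotein gene, at 87.08 ± 31.3 against 21.67 ± 7.01 (log2 1.94 ± 0.34), SPI1, a stress-induced cell wall gene, at 54.95 ± 9.21 against 13.89 ± 4.25 (1.94 ± 0.34), and PMT1, a protein mannosyltransferase gene, at 74.23 ± 1.58 against 20.96 ± 10.7 (1.89 ± 0.35). APA1 (1.81), TDA4 (1.78), the kinetochore gene CTF19 (1.72) and SFT1 (1.51) were higher as well, and so was a region near the arginine tRNA gene YNCJ0011W (2.54). Lower ones included the valine tRNA gene YNCK0014W (−1.46) and the IKI3/VAC14 promoters (−1.20).

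This made 41 regions higher and 5 lower in YJM789, or 21 and 11 with library medians set equal. A peak in at least 2 YJM789 libraries stood at 9 of the 41, and input above ChIP in at least 2 of them also at 9. Of the 41, 8 were mitochondrial or the 2-micron plasmid. Drug resistance promoters were enriched among the higher regions (2 of 3 tested, adjusted p = 0.00635, Fisher's exact test). Adjusted over the list alone, 2 were higher and 1 lower (YRR1), against 2 and 0 over all regions, and ATP7 and TPS1 were higher on the list counts of respiration and general stress. The 46 calls became 29, 27 and 92 without YJM789 replicates 1, 2 and 3, and 29 without S96 replicate 3. SNQ2, HPF1, SPI1, PMT1, APA1, TDA4 and the regions near YNCJ0011W and COB kept the call with each library left out (8 of 12 named higher), and 1 of 5 named lower did. Under all other settings too, HPF1 and the region near COB kept it (2 of 12). PMT1 and APA1 lost it in the m2 set, where the region near YNCJ0011W turned to −0.51, and SPI1 and TDA4 lost it with empty values as 0. SNG1 lost it without YJM789 replicate 1 (0.88, adjusted p = 0.0536) or 2 (0.86, 0.0658) or S96 replicate 1 (0.74, 0.0774), and with library medians set equal SNQ2 stood at 0.32 (adjusted p = 0.0518) and SNG1 at 0.73 (0.0508). In a fit of only these 2 groups neither passed (adjusted p = 0.075 and 0.0509).

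S96-I775E and S96 in YPD differ by the single amino acid change, but also in the input library of each group. The background that the rise subtracts differed between them. Its median over nuclear regions (ChIP minus input coverage) was −10.85 ± 1.81 for S96 and 5.84 ± 1.92 for S96-I775E (SD, n = 3 libraries). The mutant had less signal at 3 of the Yrr1 regions. IRT1 was lower by the firmest margin of this comparison, at −1.78 ± 0.11 (adjusted p = 1.74e-12), YRR1 stood at −2.12 ± 0.35 (adjusted p = 0.000318) and SNG1 at −0.98 ± 0.21 (adjusted p = 0.00503), while SNQ2 did not pass (−0.10 ± 0.09, adjusted p = 0.536). At YRR1 the MACS2 fold was not lower in the mutant (1.73, 1.55 and 1.8 against 1.67, 1.57 and 1.42 by library), and the ChIP pileup over the lowest background of the library was 3.32 ± 0.25 against 4.4 ± 0.21. At SNG1 the folds overlapped (1.97 and 1.71 in the 2 mutant libraries with a peak against 2.1, 1.95 and 1.79). CHD1 was lower too, at 21.25 ± 5.24 against 74.49 ± 7.25 (−1.78 ± 0.31), as were the bodies of PAT1, a messenger RNA decay gene (−1.63), and of the ribosomal protein genes RPS11A (−1.64), RPL18B (−1.59) and RPP0 (−1.56). Highly transcribed gene bodies made up 15 of the 67 lower regions (p = 0.00154, one-sided Fisher's exact test), among them ENO2, TDH3 and TEF1. The promoter of COX5A, a subunit of cytochrome c oxidase, was lower too. Among the regions higher in the mutant, 12 of 25 lay at tRNA genes (200 of 1350 tested do; p = 7.19e-05, Fisher's exact test), with the valine tRNA gene YNCM0023C at 64.63 ± 13.8 against 18.34 ± 5.18 (1.78 ± 0.34) and the isoleucine tRNA gene YNCN0015W at 70.23 ± 10.2 against 22.17 ± 2.72 (1.62 ± 0.28).

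The totals were 25 higher and 67 lower, and 57 and 25 with library medians set equal, so the balance of directions turned with that scaling. It turned on a linear scale (405 and 104) and with empty values as 0 (94 and 68) as well, and without S96 replicate 3 (28 and 23). Only 1 of the 25 higher regions had a peak in at least 2 mutant libraries, 8 of the 67 lower ones had one in S96, and 8 of the 25 were mitochondrial or the plasmid. MACS2 called input above ChIP in at least 2 libraries of the group with the higher rise at 9 of the 25 and 23 of the 67. Nuclear peaks of that kind averaged 385.7 per library for S96 in YPD and 22.0 for S96-I775E in YPD. Drug resistance regions numbered 0 higher and 2 lower over all regions and adjusted over the list alone. On the latter count COX5A (also over all) and TPS1 were lower. The 92 calls became 40 and 51 without S96 replicates 2 and 3, and 53, 60 and 52 without S96-I775E replicates 1, 2 and 3. IRT1, YRR1, SNG1, CHD1, PAT1, RPL18B and RPP0 kept the call with each library left out (7 of 11 named lower), as did YNCM0023C, YNCN0015W and the region near YNCK0019W (3 of 10 named higher). Under all other settings too, 4 of 11 and 3 of 10 did. In the m2 set YRR1 stood at −1.45 with an adjusted p of 0.0529.

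With 4NQO, the mutant again had less signal than S96 at IRT1 (−1.06 ± 0.11, adjusted p = 1.54e-07) and more at SNQ2 (0.39 ± 0.09, adjusted p = 0.013). SNG1 (−0.51 ± 0.21, adjusted p = 0.236) and YRR1 (−0.78 ± 0.35, adjusted p = 0.298) did not pass. Lower regions included the DCD1 promoter at SUF8, at 18.91 ± 4.47 against 66.2 ± 7.59 (−1.77 ± 0.30), the bodies of FAA1, a fatty acid activation gene (−1.64), TKL2, a transketolase gene (−1.54), and SAM2 (−1.17), and the promoters of the amino acid sensor PTR3 (−1.40) and PEX25 (−1.34). FAA1 has values in 2 of 3 S96 libraries, turned to 0.21 with empty values as 0, and kept its call in 1 of 6 fits with a library left out (all but that without S96 replicate 3 ended it). Higher ones were the promoters of PUT7 (1.78) and GAT1, a nitrogen regulator (1.59), the body of STE20, a kinase of the mating pathway (1.55), the ribosomal DNA (RDN5-2, 1.44) and mitochondrial regions at 21S_RRNA (1.23), near COB (1.51) and near BI3 (0.97). At the ribosomal DNA and at these mitochondrial regions MACS2 called input above ChIP in the 3 mutant libraries.

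In total 17 regions were higher and 8 lower (20 and 7 with equal medians), 9 of the 17 mitochondrial or the plasmid. The balance turned with MACS2 ChIP peaks only (3 and 4) and with nuclear regions only (6 and 7). Of the main calls, 1 of 17 and 1 of 8 had a peak in at least 2 libraries of the higher group. Input above ChIP in at least 2 of those libraries stood at 11 of 17 and 0 of 8. Drug resistance regions were 1 higher and 0 lower over all, and 1 and 2 (SNG1 and YRR1) adjusted over the list alone. The 25 calls became 13 without S96-I775E replicate 1. IRT1, DCD1, RDN5-2, 21S_RRNA and the regions near COB, YLR462W and BI3 kept the call with each library left out, which is 7 of 19 named. All 7 kept it under the other settings that held them, but the mitochondrial ones are absent from the fit of nuclear regions only. SNQ2 lost it without S96 replicate 2 (adjusted p = 0.074) or S96-I775E replicates 1 (0.0624) and 3 (0.0683). It also lost it, at 0.39, with empty values as 0 (adjusted p = 0.113), in a fit of only these 2 groups (0.13), in the m2 set (0.063), and with MACS2 ChIP peaks only (0.0853) or nuclear regions only (0.0851).

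Set directly against YJM789, S96-I775E had less signal at IRT1 in YPD (−1.22 ± 0.11, adjusted p = 1.59e-08) and in 4NQO (−0.97 ± 0.11, adjusted p = 2.1e-06), and in 4NQO less at SNG1 (−1.41 ± 0.21, adjusted p = 0.000192). SNQ2 passed in neither medium (−0.24, adjusted p = 0.139, and −0.09, 0.614), nor did YRR1 (−0.48, 0.544, and 0.06, 0.954). In YPD, lower regions included SSM4 (−1.68), the cell wall gene TIP1 (−1.42), GCV2, a glycine cleavage gene (−1.36), and YAT1 (−1.16), and higher ones a region near the methionine tRNA gene EMT1 (1.93), the 2-micron plasmid (1.58), PFK2, a phosphofructokinase gene (1.36), and RDN5-2 (1.35). In 4NQO, lower regions included SPI1 (−1.99), VMA3, a subunit of the vacuolar proton pump (−1.65), APA1 (−1.64), TPI1, the triose phosphate isomerase gene (−1.61), CYC3, the cytochrome c heme lyase gene (−1.52), and HPF1 (−1.51), and higher ones lay near RPL11A (1.39) and the histidine tRNA gene YNCG0003C (1.47). Of the 20 higher regions in YPD, 10 lay at tRNA genes (p = 0.000196, Fisher's exact test).

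These comparisons gave 20 higher and 9 lower in YPD (31 and 6 with equal medians) and 9 higher and 43 lower in 4NQO (25 and 22). A peak in at least 2 libraries of the higher group stood at 2 of 20 and 1 of 9, and at 1 of 9 and 14 of 43. Input above ChIP in at least 2 of those libraries stood at 7 of 20 and 1 of 9, and at 2 of 9 and 1 of 43. Drug resistance regions were 0 higher and 0 lower in YPD over all, and 0 and 1 (SNQ2) adjusted over the list alone, and in 4NQO 0 and 1 (SNG1) on both counts, where RPL29 of the highly transcribed list was lower too. The 29 calls in YPD became 10 and 18 without YJM789 replicates 2 and 3, and 16, 13 and 14 without S96-I775E replicates 1, 2 and 3. The 52 in 4NQO became 29, 11 and 93 without YJM789 replicates 1, 2 and 3, and 22, 14 and 24 without S96-I775E replicates 1, 2 and 3. With each library left out, 5 of 19 named regions kept the call in YPD (IRT1, EMT1, the plasmid, PFK2 and RDN5-2), and 5 of 21 in 4NQO (IRT1, SNG1, SPI1, TPI1 and the region near YNCG0003C). Under all other settings too, 5 of 19 and 2 of 21 did.

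The effect of 4NQO was then measured within each allele. With the YJM789 allele, SNG1 rose from 70.92 ± 9.11 to 132.8 ± 9.05 (log2 0.90 ± 0.21, adjusted p = 0.00757) and SNQ2 from 196.3 ± 4.78 to 242.0 ± 28.4 (0.29 ± 0.09, adjusted p = 0.0441), while IRT1 (0.07, adjusted p = 0.792) and YRR1 (−0.19, 0.808) did not pass. The MACS2 fold at SNQ2 went the other way in every library, with 3.68, 3.75 and 3.75 in YPD and 3.17, 3.32 and 2.81 in 4NQO. Signal rose furthest at chromosome ends and repeated DNA: YNR077C (XIV 783435 to 784407) from 19.62 ± 2.97 to 153.5 ± 43.8 (2.87 ± 0.29), the end of chromosome III near YCL075W from 38.94 ± 4.75 to 173.9 ± 43.3 (2.11 ± 0.23), the 2-micron plasmid (2.39) and the ribosomal DNA at RDN5-2 (2.17). At the plasmid and at RDN5-2 MACS2 called input above ChIP in the 3 libraries in 4NQO. HPF1 (1.76), the promoter of MET17, a sulfur assimilation gene (1.72, with a leucine tRNA gene in the region), and regions near SOK2, a regulator of filamentous growth (1.75), and EMT1 (1.99) rose as well. YGR050C (−1.52), HOS2/IME4 (−1.32), YAP3 (−1.27) and GCV2 (−1.11) fell. HOS2/IME4 has values in 2 of 3 libraries in YPD, turned to 0.48 with empty values as 0, and kept its call in 1 of 6 fits with a library left out, that without 4NQO replicate 3.

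With the S96 allele, IRT1 fell in 4NQO by 0.40 ± 0.11 on the log2 scale (adjusted p = 0.0433), and SNQ2 (−0.04, adjusted p = 0.841), SNG1 (−0.58, 0.116) and YRR1 (−0.99, 0.116) did not pass. Signal rose at the DCD1 promoter (1.69 ± 0.30), at YAR010C, an open reading frame of a Ty element (2.06 ± 0.37, with an alanine tRNA gene), at YNCN0015W (1.41) and near YCL075W (1.39 ± 0.23). It fell near the cell wall gene HSP150 (−1.47), at UTH1 (−1.37), at the ribosomal protein genes RPS14A (−1.27) and RPS4B (−1.25), and near CCW12 (−1.22). With S96-I775E, SNQ2 rose from 166.1 ± 16.3 to 226.0 ± 8.86 (0.45 ± 0.09, adjusted p = 0.00651), and IRT1 (0.31, adjusted p = 0.14), SNG1 (−0.12, 0.84) and YRR1 (0.36, 0.678) did not pass. MET17 (1.69), YNR077C (46.13 ± 16.8 to 128.7 ± 19.8), a region near GEX2, a glutathione exchanger gene (1.62), and one near YKL097C (1.82) rose. The translation factor gene CDC33 (−1.38), the region near SNR52 (−1.72) and PFK2 (−1.11) fell.

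Within YJM789, 83 regions rose and 9 fell (35 and 16 with equal medians), within S96 19 and 16 (26 and 10), and within S96-I775E 26 and 9 (15 and 9). The balance in S96 turned with a pseudocount of 5 (20 and 23), in a fit of only the 2 groups (11 and 18) and without YPD replicate 1 (14 and 16). A peak in at least 2 libraries in 4NQO stood at 30 of 83, 2 of 19 and 5 of 26 of the rising regions. Input above ChIP in at least 2 stood at 12, 5 and 3. Of the falling regions, 1 of 9, 10 of 16 and 0 of 9 had input above ChIP in at least 2 libraries in YPD, UTH1 in S96 among them. Drug resistance promoters were enriched among those rising in YJM789 (SNG1 and SNQ2, adjusted p = 0.0399, Fisher's exact test), with 2 up and 0 down over all regions and adjusted over the list alone. In S96 the counts were 0 and 0 over all, and 0 and 2 (SNG1 and YRR1) over the list alone, and in S96-I775E 1 and 0 on both. TPS1 and RPL29 rose in YJM789 on both counts. Adjusted over the list alone, ATP7 rose in YJM789, NDI1 in S96-I775E, and TPS1 fell in S96. By promoter, a tested DNA damage region (1) or oxidative stress region (2) passed in 0 of the 11 comparisons of this report, over all or adjusted over the list alone. By gene body, the oxidative stress gene AHP1 lay in a region that passed in 3 comparisons. It was lower in YJM789 than in S96 in YPD, fell in 4NQO in S96, and had a larger response in YJM789 than in S96. The list itself did not pass in these (adjusted p = 0.281, 0.398 and 0.437, Fisher's exact test).

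Without single libraries the 92 calls in YJM789 became 43, 54 and 52 (YPD replicates 1, 2 and 3) and 51 and 43 (4NQO replicates 1 and 2). The 35 in S96 became 17 without YPD replicate 3 and 15 without 4NQO replicate 3. The 35 in S96-I775E became 6, 9 and 13 without YPD replicates 1, 2 and 3 and 8, 13 and 19 without 4NQO replicates 1, 2 and 3. With each library left out, 11 of 12 named rising regions of YJM789 kept the call (all but SNQ2) and 2 of 9 falling ones (YGR050C among them). In S96, YAR010C, DCD1 and the regions near YNCK0019W and YCL075W did, 4 of 10, and 0 of 11 falling ones. In S96-I775E, YNR077C and the region near YKL097C did, 2 of 11, and 0 of 9. Under all other settings too, 9 of 12 rising and 0 of 9 falling regions kept the call in YJM789, 4 of 10 and 0 of 11 in S96, and 0 of 11 and 0 of 9 in S96-I775E. SNQ2 in YJM789 stood at 0.08 with library medians set equal (adjusted p = 0.703), IRT1 in S96 at −0.27 (0.213) and SNG1 in YJM789 at 0.68 (0.0583). SNQ2 in YJM789 also lost its call without any 1 library but 4NQO replicate 3 (adjusted p from 0.0844 to 0.245). IRT1 in S96 lost it without any but 4NQO replicate 1 (from 0.0659 to 0.153). SNQ2 in S96-I775E lost it without YPD replicate 2 (0.38, adjusted p = 0.0586) or with empty values as 0 (0.068). Empty values as 0, the m2 set, MACS2 ChIP peaks only and nuclear regions only each ended the calls of SNQ2 in YJM789 (adjusted p from 0.0921 to 0.236) and of IRT1 in S96 (from 0.0779 to 0.0855). A fit of only the 2 groups also ended that of SNQ2 in YJM789 (0.0517).

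Rising regions were shared between alleles, whose libraries are separate, but the responses over all 1350 regions were nearly uncorrelated (Spearman 0.05 for YJM789 and S96, 0.02 for YJM789 and S96-I775E, 0.04 for S96 and S96-I775E). Of falling regions the same pairs shared 1, 0 and 0. Of nuclear regions rising in 4NQO, YJM789 and S96 shared 6 (0.78 if independent, p = 5.27e-05, one-sided exact hypergeometric test). YJM789 and S96-I775E shared 8, among them SNQ2, MET17 and the region near GEX2 (1.29, p = 1.64e-05, same exact test), and S96 and S96-I775E shared 3 (0.24, p = 0.00142). These 3 nuclear regions, near YCL075W, near YHR219W and at YNR077C, rose with every allele and all lie at chromosome ends. Mitochondrial regions at COX1, near BI3 and near COX2, left out of the nuclear counts, rose with every allele as well. Mitochondrial or plasmid regions were 8 of the 83 rising in YJM789, 5 of 19 in S96 and 3 of 26 in S96-I775E. In 4NQO, MACS2 listed ChIP peaks in 3, 1 and 3 libraries of YJM789, S96 and S96-I775E near YCL075W. Near YHR219W these were 2, 0 and 0, and at YNR077C 3, 0 and 3. In YPD it called input above ChIP in 2, 3 and 0 libraries near YCL075W. Near YHR219W these were 1, 0 and 0, and at YNR077C 1, 2 and 0. The region near YHR219W has 6 copies elsewhere by blastn, and those near YCL075W and at YNR077C have 0. Within 15 kb of an end, 12 of 52 tested regions rose in YJM789 (p = 3.63e-05, Fisher's exact test), 4 in S96 (p = 0.00494) and 5 in S96-I775E (p = 0.00248), or 13 different regions. Regions near YAL064W-B (1.56), IMD2, an inosine monophosphate dehydrogenase gene (1.62), and COS2 (1.32) passed in YJM789 and not in the other alleles, but their response did not differ from that in S96 past the threshold (near YAL064W-B adjusted p = 0.128, near IMD2 0.228, near COS2 0.067). At YNR077C it was larger in YJM789 than in S96, by 1.72 (adjusted p = 0.0193), a call that ended with library medians set equal (1.37, adjusted p = 0.0907). The region near YHR219W lost its call in S96 without YPD replicate 3 (1.34, adjusted p = 0.0513) or 4NQO replicate 3 (1.28, 0.0638), and in S96-I775E without any 1 of its 6 libraries (adjusted p from 0.0537 to 0.128). With empty values as 0 it also lost it in S96-I775E (0.112), as did YNR077C (0.0614).

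**Figure D3:**
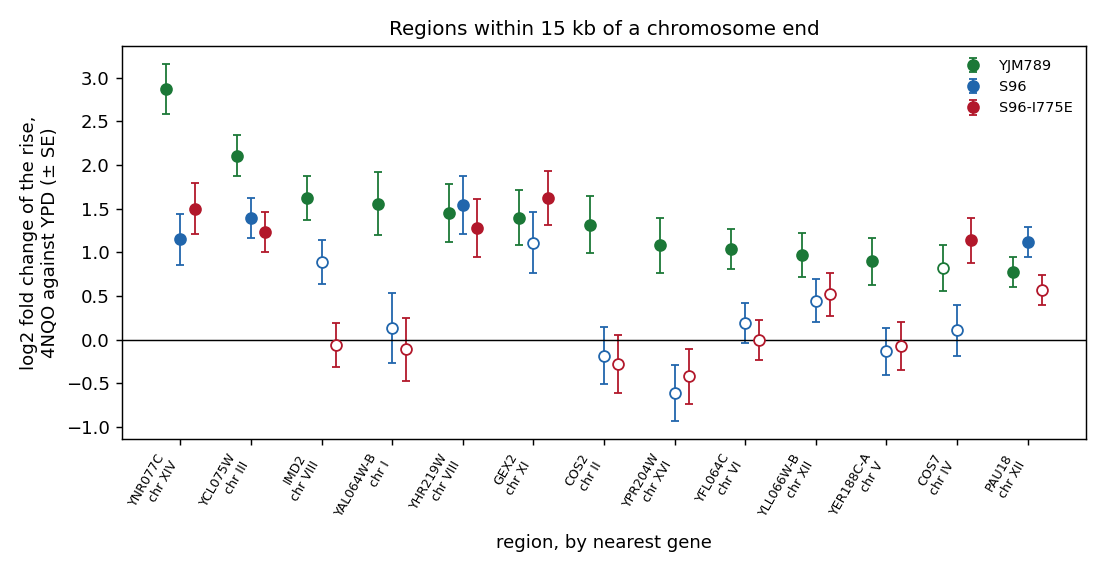
Log2 fold change of the rise, 4NQO against YPD, with SE (n = 3 libraries per medium), at the 13 regions within 15 kb of a chromosome end that rose in at least 1 allele (x axis, by nearest gene; colour, allele; filled, past the threshold). Regions near YCL075W and YHR219W and at YNR077C pass with all 3 alleles.

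Whether the response to 4NQO differs between alleles was tested directly. The response at SNG1 was larger with YJM789 than with S96 by 1.48 ± 0.30 (log2, adjusted p = 0.0074), rising in one and not passing in the other, and those at SNQ2 (0.33, adjusted p = 0.117), IRT1 (0.47, 0.082) and YRR1 (0.80, 0.371) did not differ past the threshold. Further responses larger in YJM789 were those of HPF1 (2.79 ± 0.49), TPI1 (2.42 ± 0.42), EMI2, a hexokinase family gene (2.44 ± 0.53), VMA3 (2.42 ± 0.51) and SFT1 (2.32 ± 0.51), and the DCD1 promoter at SUF8 went the other way (−2.35 ± 0.43). S96-I775E and S96 differed in their response at IRT1 (0.72 ± 0.16, adjusted p = 0.0147) and SNQ2 (0.49 ± 0.12, adjusted p = 0.0377), and not past the threshold at SNG1 (0.46, 0.446) or YRR1 (1.34, 0.141). RPS14A (2.33 ± 0.44) and TDH2, a glyceraldehyde phosphate dehydrogenase gene (2.09 ± 0.41), responded more in S96-I775E, and DCD1 (−2.62 ± 0.43), PEX25 (−2.26 ± 0.45) and the proteasome gene RPT2 (−2.19 ± 0.47) less.

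The YJM789 and S96 responses differed at 53 regions (48 more in YJM789, 5 less), or 4 and 5 with library medians set equal, and those of S96-I775E and S96 at 35 (26 and 9), or 6 and 13. The balance of the latter also turned on a linear scale (39 and 75) and with empty values as 0 (19 and 44), and was even in the m2 set (7 and 7). Highly transcribed gene bodies made up 13 of the 48 (p = 0.000468, Fisher's exact test). By gene body the general stress list passed in this set as well (SPI1 and TPS1, adjusted p = 0.0215, Fisher's exact test). With equal medians neither member kept its own call. SPI1 went from 2.49 to 2.14 (adjusted p = 0.0559) and TPS1 from 1.60 to 1.25 (0.109). Of the smaller responses, tRNA genes made up 4 of the 5 and 6 of the 9 (p = 0.00207 and 0.000561, Fisher's exact test). The drug resistance count was 1 larger over all regions and 2 (SNG1 and SNQ2) adjusted over the list alone in YJM789, and 1 and 2 (SNQ2 and YRR1) in S96-I775E. TPS1 of the general stress list was larger in YJM789 on both counts and in S96-I775E on the list alone, as was RPL29 in YJM789. With equal medians the YJM789 difference at SNG1 stood at 1.14 (adjusted p = 0.0559), and the S96-I775E differences at IRT1 at 0.51 (0.117) and at SNQ2 at 0.28 (0.27). With empty values as 0 IRT1 (0.057) and SNQ2 (0.0876) missed the threshold as well. SNQ2 also lost its call in a fit of only the groups compared (0.0528), in the m2 set (0.144), and with MACS2 ChIP peaks only (0.0745) or nuclear regions only (0.088). The SNQ2 difference lost its call without S96 YPD replicate 1 or 3, S96 4NQO replicate 1 or 2, S96-I775E YPD replicate 2 or 3, or S96-I775E 4NQO replicate 1 or 3 (adjusted p from 0.052 to 0.0861). The 53 became 25 and 26 without YJM789 YPD replicates 1 and 3, 29, 29 and 96 without YJM789 4NQO replicates 1, 2 and 3, 21 without S96 YPD replicate 3 and 34 without S96 4NQO replicate 1. The 35 became 17 and 21 without S96 YPD replicates 2 and 3, 13 without S96 4NQO replicate 3, 20 and 16 without S96-I775E YPD replicates 2 and 3, and 19 and 23 without its 4NQO replicates 1 and 3. With each library left out, 7 of 16 named regions kept the first call (HPF1, EMI2, TPI1, VMA3, SFT1, SNG1 and DCD1) and 8 of 21 the second (RPS14A, YGR079W, TDH2, IRT1, DCD1, PEX25, RPT2 and the region near SNR52). Under all other settings too, 2 of 16 and 4 of 21 did.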

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

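Of the tests in this part, the restriction to peak lists of the same kind, the comparisons with equal library medians, the splits of the samples, and the comparison with highly transcribed genes lacking a peak were chosen only after the results were seen.

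The response to 4NQO differed between alleles by a direct test. It differed between YJM789 and S96 at 53 regions. Besides SNG1/YPP1 (1.48 on the log2 scale), the named ones were larger in YJM789 at HPF1 (2.79), SPI1 (2.49), EMI2 (2.44), TPI1 (2.42), VMA3 (2.42), SFT1 (2.32), APA1 (2.24), TAE1 (2.2), YRF1-4 (2.19) and near CCW12 (2.14). They were smaller at DCD1 (−2.35), YNL146C-A (−2.11), JJJ2 (−2.01), RPT2 (−1.75) and near the tRNA gene IMT4 (−1.42). With empty values as 0 YNL146C-A turned to 1.40, and in the m2 set JJJ2 to 0.34. Between S96-I775E and S96 the response differed at 35 regions. It was larger in S96-I775E at RPS14A (2.33), GAT1 (2.23), YGR079W (2.2), YAP3 (2.19), YPL113C (2.12), TDH2 (2.09), near YKL097C (2.02), near SRM1 (1.96), PRE7 (1.90), CHD1 (1.89), IRT1 (0.72) and YDR010C/SNQ2 (0.49). It was smaller at DCD1 (−2.62), near YNCE0028C (−2.52), near SNR52 (−2.47), PEX25 (−2.26), RPT2 (−2.19), YNCM0023C (−2.14), near SNR40 (−1.67), YNCN0015W (−1.60) and near YNCK0019W (−1.60). With empty values as 0 PRE7 turned to −0.09.

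The excess of larger over smaller responses in YJM789 was weighed against a scaling of whole libraries. Among all 1350 tested regions, 276 had a larger and 33 a smaller response by more than 2 SE. With library medians set equal these were 121 and 115 (51.3% larger of 236, exact interval 44.7 to 57.8, regions counted as independent). Setting medians equal moves the directions toward balance whatever had shifted them (by 0.36 over all tested regions). A broad gain of binding by the YJM789 allele would shift the medians as a scaling would. The count therefore cannot tell these explanations apart, and both stay open. At single regions the scaling took 0.32 to 0.42 from each of the 48 called larger responses, whose median went from 1.81 (quartiles 1.55 to 2.13) to 1.45 (1.20 to 1.75), with a median SE of 0.45. Of the 53 calls 44 ended, as these smaller differences moved their adjusted p past 0.05 (to between 0.0536 and 0.198). VMA3 went from 2.42 to 2.07, SPI1 from 2.49 to 2.14, EMI2 from 2.44 to 2.08 and PDC1 from 1.24 to 0.89. Among the 9 that kept the call were HPF1 (2.79 and 2.44), TPI1 (2.42 and 2.07), RPL4A (2.13 and 1.78), DCD1 (−2.35 and −2.70) and RPT2 (−1.75 and −2.09). Of 100 splits of the libraries, 1, the real one, gave as many as 53 regions (highest other 26), and 1 gave as many as 35 for S96-I775E against S96 (highest other 4). The other splits exchanged YPD and 4NQO libraries within each allele. Such groups mix media and inputs, which can widen the spread within them and lower the calls. The splits therefore cannot exclude chance as a source of these counts. An error of an input shared by the 3 libraries of a group would follow the real split and is not excluded.

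Chromosome ends rose in 4NQO with all 3 alleles, at 13 regions in all. Reads shared between near-identical ends were tested by looking for copies elsewhere: 8 of the 13 had none (61.5%, exact interval 31.6 to 86.1), against 10 of the 39 other end regions (p = 0.996, one-sided Fisher's exact test, for more copies among the 13). The interval reaches below 50%, so sharing could still account for part of the pattern. An error of the single input per group cannot be told apart from a change of ChIP. The ChIP level in YPD is known almost only where MACS2 called input above ChIP, which is the condition that such an error would bring about, so the limit of 1 set beforehand for the ratio of the media was wrong. Levels from the same kind of peak list in both media exist at 1 of the 13 regions, near YCL075W with S96-I775E (ratio 1.29). Biological change of chromosome ends under the drug, with or without Yrr1, stays open, since no untagged strain was analysed.

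Peaks at tRNA genes and in bodies of highly transcribed genes were weighed against background signal at active loci. At tRNA genes 14 of 76 peak regions held the sequence WCCGYKKWW (18.4%), against 12.6% of random placements (permutation p = 0.0886) and 28 of 197 regions (14.2%) at tRNA genes without a peak (p = 0.246, Fisher's exact test), so background may account for these peaks. In bodies of highly transcribed genes 22 of 69 did (31.9%), against 18.6% at random (permutation p = 0.004) and 20 of 107 (18.7%) without a peak (p = 0.0349, Fisher's exact test). The share was thus higher than in both. However, the intervals without a peak all had the median length and sat at gene middles, and random placement does not match base composition. The sequence is also short and loose, so the test cannot decide whether background accounts for these peaks. Binding by Yrr1 at part of these genes stays open as a hypothesis, and a control from an untagged strain would test it.

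For the 9 comparisons of 2 groups, 3 against 3 libraries make 10 splits, too few for a share under 0.05. In each, 1 split, the real one, gave the most regions. The other splits mix the 2 compared groups and their inputs, which can widen the spread and lower the calls. Their low counts therefore cannot exclude chance. YJM789 against S96 gave 28 in YPD (highest other 1) and 46 in 4NQO (3). S96-I775E gave 92 (0) and 25 (1) against S96, and 29 (1) and 52 (2) against YJM789. The 4NQO effect gave 92 (1) in YJM789, 35 (1) in S96 and 35 (0) in S96-I775E.

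The tests between groups include regions without a ChIP peak, as 987 of the 1350 tested had a MACS2 ChIP peak. Nuclear peaks with input above ChIP averaged 132.0 per library for YJM789 in YPD, 29.67 for YJM789 in 4NQO, 385.7 for S96 in YPD, 54.33 for S96 in 4NQO, 22.0 for S96-I775E in YPD and 27.33 for S96-I775E in 4NQO, each over 3 libraries that share 1 input.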

How the results depend on the processing

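Chosen only after the data were seen were the m2 set, equal library medians, the linear scale, empty values as 0, MACS2 ChIP peaks only, nuclear regions only, and a peak in 3 of 3 libraries. The count-based alternatives planned (other size factors, a count test, at least 20 reads in 3 libraries) were not run, because no counts are given. Over the 255 results for named regions, other settings left the side of the threshold the same in 2002 cases. They took the result below it in 339 and above it in 10, and turned the direction of a result past it in 12. The 255 include results for IRT1, SNQ2, SNG1 and YRR1 that had not passed. Those that stayed so count as the same, and their direction was not checked. Leaving out single libraries left 1126 the same, took 558 below and 2 above. Replicate numbers do not pair the media (correlations of library residuals from −0.066 to 0.07). Read depth is unknown, so its limit on any of these counts could not be computed.

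Counts of regions past the threshold are given here in the order YJM789 against S96 in YPD and 4NQO, S96-I775E against S96 in YPD and 4NQO, S96-I775E against YJM789 in YPD and 4NQO, 4NQO in YJM789, S96 and S96-I775E, and the response differences of YJM789 and S96-I775E from S96. The main counts were 28, 46, 92, 25, 29, 52, 92, 35, 35, 53 and 35. An adjusted p below 0.005 left 1, 13, 18, 11, 10, 4, 29, 12, 0, 4 and 1, as a stricter threshold must leave fewer. For the other settings the cause was not tested. On a linear scale of the strongest point there were 152, 408, 509, 79, 113, 206, 725 and 455, then for the response differences 108 and 114. Empty values as 0 gave 92, 26, 162 and 15 for the first 4, 13 for S96-I775E against YJM789 in 4NQO, 140 and 1 for 4NQO in S96 and S96-I775E, and 85 and 63 for the response differences. MACS2 ChIP peaks only gave 15, 27, 56, 7, 13, 34, 58, 19 and 22, and 19 for the last. The m2 set gave 16 for YJM789 against S96 and 57 for S96-I775E against S96 in YPD, 22 for S96-I775E against YJM789 in 4NQO, 14 for 4NQO in S96-I775E and 14 for its response difference. Equal library medians gave 16 for YJM789 against S96 in YPD, 51 for 4NQO in YJM789, and 9 and 19 for the response differences. A fit of only the groups compared gave 17 and 30 for YJM789 against S96 and S96-I775E against YJM789 in 4NQO, 61 for 4NQO in YJM789 and 22 for the last. Nuclear regions only gave 13 for S96-I775E against S96 in 4NQO and 15 against YJM789 in YPD. A replicate block gave 26, 51, 96, 26, 30 and 51 over all groups and 84, 36, 34, 41 and 23 within allele. Other counts under these settings, other pseudocounts, filters, a fold of at least 2 and merged windows stayed within 1.5 times.

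The balance of higher and lower regions turned, or was no longer seen, as follows, with the cause not tested. YJM789 against S96 in YPD (7 and 21) gave 53 and 39 with empty values as 0 and 9 and 7 with equal library medians. It also gave 1 and 0 at an adjusted p below 0.005, and 3 and 3 without S96 replicate 2. S96-I775E against S96 in YPD (25 and 67) gave 94 and 68 with empty values as 0 and 57 and 25 with equal medians. It also gave 405 and 104 on a linear scale, 11 and 7 at an adjusted p below 0.005, and 28 and 23 without S96 replicate 3. In 4NQO (17 and 8) it gave 3 and 4 with MACS2 ChIP peaks only and 6 and 7 with nuclear regions only. S96-I775E against YJM789 in 4NQO (9 and 43) gave 25 and 22 with equal medians. The 4NQO effect in S96 (19 and 16) gave 20 and 23 with a pseudocount of 5, 14 and 14 at a fold of at least 2, 11 and 18 in a fit of only the groups compared, and 14 and 16 without YPD replicate 1. The YJM789 response difference (48 and 5) gave 4 and 5 with equal medians. That of S96-I775E (26 and 9) gave 6 and 13 with these, 19 and 44 with empty values as 0, 39 and 75 on a linear scale, 7 and 7 in the m2 set, and 0 and 1 at an adjusted p below 0.005. The 4NQO effect in S96-I775E (26 and 9) gave 0 and 0 at that threshold.

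Leaving out 1 library at a time, the 11 counts ranged from 5 to 33, 27 to 92, 40 to 78, 13 to 21, 10 to 21, 11 to 93, 43 to 111, 15 to 35, 6 to 19, 21 to 96 and 13 to 37. Bound regions ranged from 3 to 4 for YJM789 in YPD, 21 to 271 in 4NQO, 13 to 69 and 9 to 41 for S96, and 13 to 21 and 16 to 23 for S96-I775E.

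Bound regions (4, 273, 75, 61, 36 and 31) fell to 2, 42, 5, 5, 2 and 8 at a fold of at least 2, and from the second on to 20, 11, 8, 6 and 14 with a peak in 3 of 3 libraries, as fewer regions can meet these. With q 10 times stricter the last 4 fell to 40, 35, 19 and 20 for S96 and S96-I775E. Shared regions at a fold of at least 2 numbered 2, 2 and 2 for the 3 pairs in YPD, 3, 3 and 5 for those in 4NQO, and 2 and 2 between media for S96 and S96-I775E. With the stricter q they were 21, 8 and 15 in 4NQO and 9 between media in S96, and with centres within 100 bp S96 and YJM789 shared 22 in 4NQO. The share of CisGenome regions with a MACS2 region (36.8%) was 15.4% at a fold of at least 2, 29.2% at the stricter q, 18.8% with centres within 100 bp and 9.6% with 50% of both regions. Promoters of 250 and 1000 bp held 6.5% and 57.3% of regions (20.7% at 500 bp). List tests past the threshold (8) were 0 and 4 with these lengths and 4 with the upper part of regions by fold.

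For named results past the threshold in the main fit, directions that turned, with the cause not tested, were these. With empty values as 0, YNL146C-A stood at −0.17 for YJM789 against S96 in YPD and at 1.40 in the response difference, the region near HEM13 at 0.26 for S96-I775E against S96 in YPD, FAA1 at 0.21 in 4NQO, YHC3 at 0.42 for S96-I775E against YJM789 in YPD, HOS2/IME4 at 0.48 for 4NQO in YJM789, and PRE7 at −0.09 in the S96-I775E response difference. In the m2 set, the region near YNCJ0011W stood at −0.51 for YJM789 against S96 and 0.86 for S96-I775E against YJM789 in 4NQO, YGR109W-A/YGR109W-B at 0.76 for S96-I775E against YJM789 in YPD, YER135C at 0.03 for 4NQO in S96-I775E, and JJJ2 at 0.34 in the YJM789 response difference.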

Other observations

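The values in this part were picked after the results were seen, and no explanation was tested for them. Regions at tRNA genes, the sites of RNA polymerase III transcription, make up 200 of the 1350 tested. Among regions rising in 4NQO they were 19 of 83 in YJM789 (p = 0.0285, one-sided Fisher's exact test), 7 of 19 in S96 (p = 0.0146) and 4 of 26 in S96-I775E (p = 0.552), with p values not adjusted for the number of tests. Whether these shares differ between alleles was not tested.

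The ChIP pileup at the peak was divided by the lowest background value in the peak lists of its library, so that the input signal at the region does not enter. This ratio gave the same order of alleles at IRT1 as the rise did. In YPD it was 5.93 ± 0.29 for S96, 4.52 ± 0.32 for YJM789 and 2.41 ± 0.11 for S96-I775E (SD, n = 3), and in 4NQO 4.96 ± 0.48, 4.84 ± 0.19 and 2.91 ± 0.42. At SNQ2 it was 3.79 ± 0.33 for S96, 4.24 ± 0.08 for YJM789 and 3.94 ± 0.18 for S96-I775E in YPD, and 3.85 ± 0.18, 5.06 ± 0.39 and 4.74 ± 0.23 in 4NQO. The order of alleles in 4NQO was that of the rise. In YPD it was not, since the rise was lowest in S96-I775E. At SNG1 the ratio was 3.18 ± 0.23 for S96, 2.81 ± 0.40 for YJM789 and 2.06 ± 0.33 for S96-I775E (n = 2) in YPD, and 2.94 ± 0.15 (n = 2), 3.46 ± 0.32 and 2.32 ± 0.06 in 4NQO. At YRR1 it was 4.4 ± 0.21, 3.30 (n = 1) and 3.32 ± 0.25 in YPD, and 4.55 ± 0.44, 3.05 ± 0.31 and 3.59 ± 0.17 in 4NQO. The ratio of S96 at YRR1 was thus not lower in 4NQO, where the mean rise was, and alleles differed less in it than in the rise.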
